A study of Mus musculus with 34 samples.

How the data were processed

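The series holds RNA sequencing of 34 libraries of CD4- and CD8-double-negative (DN) thymocytes from C57BL6/J mice, in 8 groups. DN2 and DN3 are successive early stages, during which thymocytes commit to the T lineage. Cells carried the Bcl11b genotype +/+ (WT), flx/+ (HET) or flx/flx (HOM), together with a Cre transgene, either Lck-Cre or Vav1-iCre, and were sorted with the help of a yellow fluorescent protein (YFP) reporter. In the Lck-Cre series the labels define DN2 libraries as YFP-negative CD25-positive and DN3 libraries as YFP-positive CD25-positive, so that stage and reporter change together. The Lck HOM libraries and the Vav1-iCre libraries (here Vav) are YFP-positive CD25-positive. Per the labels, 300000 cells went into each NEBNext Ultra library, read as 50-nt single ends on a HiSeq2500. The submitters' processing notes name Trimmomatic 033, STAR 2.4.0, RSEM 1.2.25, HOMER and edgeR 3.6.8, with the builds mm9 and NCBIM37.

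The deposited values are counts. The names of both deposited tables say RPKM, but per the file headers the values are raw read counts per gene over exons from HOMER, with no normalization and 1 transcript kept per gene, and all of them are whole numbers. The deposited Length column is of another kind, the exon length of each gene in bases. Before the data were examined, limma on log2(RPKM + 1) had been chosen as the test, on the assumption that the files held RPKM. As they hold counts, the edgeR quasi-likelihood test took its place, and limma became an alternative. RPKM was computed from the counts, the lengths and the library totals for levels and filters.

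The Lck table lists 24505 gene names, and in 10 of its 25 columns (the 4 WT DN2 and the 6 HET DN3 libraries) it holds only 24479 values. The 26 values missing there belong to 13 Marc and March symbols and 13 Sept symbols, names that a spreadsheet reads as dates, and every later value stood beside the name of another gene. The names of those 10 columns were restored by moving the values down past the missing symbols. The log-scale correlation with the mean of the 15 unaffected columns rose from between 0.395 and 0.409 to between 0.980 and 0.997 over the 7154 genes between the March and Sept symbols. Over the 4991 genes from the Sept symbols on it rose from between 0.127 and 0.138 to between 0.972 and 0.996, and over the 12220 genes before the shift it was between 0.971 and 0.995. The 26 symbols and 114 genes whose order could not be settled, because of hyphens in their names, were left out, and 24365 genes remained. The HOM, WT DN3 and HET DN2 columns were not affected. Total counts in this table ran from 15772841 to 43105091 per library.

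The Vav table holds 2076 genes, in order of their change in HOM: 1102 lower and 974 higher, with a gap around no change. It is therefore a part of each library that the authors selected on these same 9 libraries, and the depth of those libraries is unknown; the listed genes had 1329826 to 2836293 counts per library. Scale factors were set by trimmed means of M values (TMM) within controls and within HOM, and between them by centring the gap on 0, which put its edges at log2 changes of -1.02 and 1.02. Levels are given as scaled counts, in CPM (counts scaled to a common library total) on that scale.

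Genes with a mean RPKM of at least 1 in at least 1 Lck group were tested, 12218 in all, using TMM normalization, a trended dispersion and all 5 groups in 1 fit. The 2076 genes of the Vav table were tested in a second fit of 3 groups. The tests are 2-sided with Benjamini-Hochberg adjustment over the genes of a comparison, and a gene was called at an adjusted p under 0.05. A test of the difference between the tables used the 2066 shared genes with a total count of at least 10. Equal replicate numbers were not taken as pairs. In WT DN3 against WT DN2, however, the residuals of all 4 equal numbers correlated across genes (r from 0.141 to 0.494, genes not being independent replicates), and a fit with the replicate number as a block called 2529 genes in that comparison, against 2622 without it. The labels do not say whether libraries of a group came from separate animals, so the p-values measure the spread between libraries and no more. For Bcl11b, Id2 and Zbtb16, the mean of log2(RPKM + 1) was compared by exact 2-sided permutation tests, adjusted over all 30 tests (3 genes in 10 comparisons).

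The genes named follow a rule. Per comparison it takes Bcl11b, Id2 and Zbtb16; the 8 higher and the 8 lower called genes with the largest fold change, a mean RPKM of at least 5 in the higher group (a scaled count of at least 100 in the Vav table) and no overlap of library values; and up to 4 members of each fixed list with the smallest adjusted p. Some genes that the rule took are not reported here. Genes outside the rule are said to have been chosen after their values were seen. The 19 fixed lists were T-lineage identity and pre-TCR signalling, stem and progenitor genes of the earliest thymocytes, Notch pathway and targets, E proteins and Id factors, NK and ILC1, ILC2 and ILC3, PLZF and innate-like T, gamma-delta T, double-positive thymocyte, B-cell, myeloid and dendritic, erythroid, thymic stroma, cell-cycle, immediate-early and heat-shock, p53 targets and apoptosis, Bcl11b cofactor, cytokine receptor and homing, and sex-linked genes. Each list was tested against the other genes with camera at a preset correlation of 0.01 and with an estimated correlation, and on its own with fry, with adjustment over the lists of a comparison. Camera was not run on the Vav table, whose genes were selected for changing. Folds against a group with no counts are lower bounds, computed against a floor of 3 counts over the group; with 1 to 3 counts, levels alone are given. Such floors cover counting error only.

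The steps were tested on simulated data of the same size. With 2-fold changes the edgeR test recovered 79% of the changed genes in HOM against WT DN3, 74% in HET against WT DN3 and 76% in HET against WT DN2, and with 4-fold changes 87%, 88% and 86%. Among 12018 unchanged genes it made 15, 5 and 3 false calls. Camera and fry called none of 20 random lists. Genes were drawn independently in the simulation, so this does not test either method where genes are correlated. The centred gap missed the simulated scale of the Vav table by -0.004 (log2), against 0.989 for the listed total and 0.325 for TMM over all listed genes. The simulated genes were picked by the same cut in both directions, so that centring on 0 was right by construction. The rule behind the real list is unknown, so this simulation does not test its scale.

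Alternatives were a pseudocount of 0.1, no filter, a filter at 5 RPKM, quantile normalization, array weights, the replicate block, a covariate for Xist, a fit of only the groups compared, a limit of 2-fold or none, and leaving out each library in turn. For calls and fold changes, the pseudocount of 0.1 and quantile normalization (of log2(RPKM + 1)) were run with limma. Array weights used limma on weighted log2 counts, so each of these settings also replaced the edgeR test. Others were chosen after seeing the data: limma as first planned, DESeq2, leaving out 6 or 8 libraries that carried RNA of other cells, the names as deposited, only the genes before the shift, only the 15 unaffected columns, and other scales for the Vav table. In 6 Lck libraries there were over 50 CPM of Clu, an epithelial transcript, and another pair had over 50 RPKM of Cd4. No deposited column was left out: the number of columns not used is 0. Within groups, no pair of libraries was a duplicate (lowest chi-square per gene 4.95, WT DN3 replicates 1 and 2; next 10.7); pairs across groups were not compared. Computations used R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and version 1.17.8 of data.table, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.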

Results

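Gene expression was measured by RNA sequencing in early thymocytes with 0, 1 or 2 floxed alleles of Bcl11b, the gene of a zinc-finger transcription factor needed for T-lineage commitment. Lck-Cre acts in thymocytes around the DN2 to DN3 transition, and Vav1-iCre acts in blood stem cells and all their descendants. The Lck series had 4 WT DN2, 5 WT DN3, 5 HET DN2, 6 HET DN3 and 5 HOM libraries, and the Vav series had 2 WT, 4 HET and 3 HOM libraries. Lck libraries held 15772841 to 43105091 counts over all genes. The Vav table holds 2076 selected genes with 1329826 to 2836293 counts per library, so its full depth is unknown. Fold changes are edgeR quasi-likelihood estimates on the log2 scale. Their standard error (SE) was computed back, as the absolute estimate divided by the square root of its F statistic. Where a group has few counts, this SE is a poor measure of the uncertainty of the fold. Levels are means with their SD across libraries, and adjusted p-values are Benjamini-Hochberg values.

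Some Lck libraries carried transcripts of other cells. In 6 of them (HET DN2 replicates 1 and 2, HET DN3 replicates 2 and 3, HOM replicates 2 and 3) Clu, an abundant transcript of secretory epithelium, stood at 132 to 1276 CPM (counts scaled to a common library total), against at most 1.29 in the other 19. The keratin genes Krt8 and Krt18 moved with it, at 100 to 880 and at 70.3 to 648 CPM in those 6, against at most 20.7 (HOM replicate 1, which also had 9.51 CPM of Krt19) and 1.19 in the others. WT DN2 replicate 2 and HET DN3 replicate 1 carried transcripts of mature T cells, with Cd4 at 69.4 and 80.3 RPKM and the chemokine gene Ccl5 at 56.9 and 29.4 RPKM. HET DN3 replicate 1 also had 884 RPKM of the globin gene Hba-a1. Main counts are therefore given also without the first 6 and without all 8 of these libraries.

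**Figure D1:**
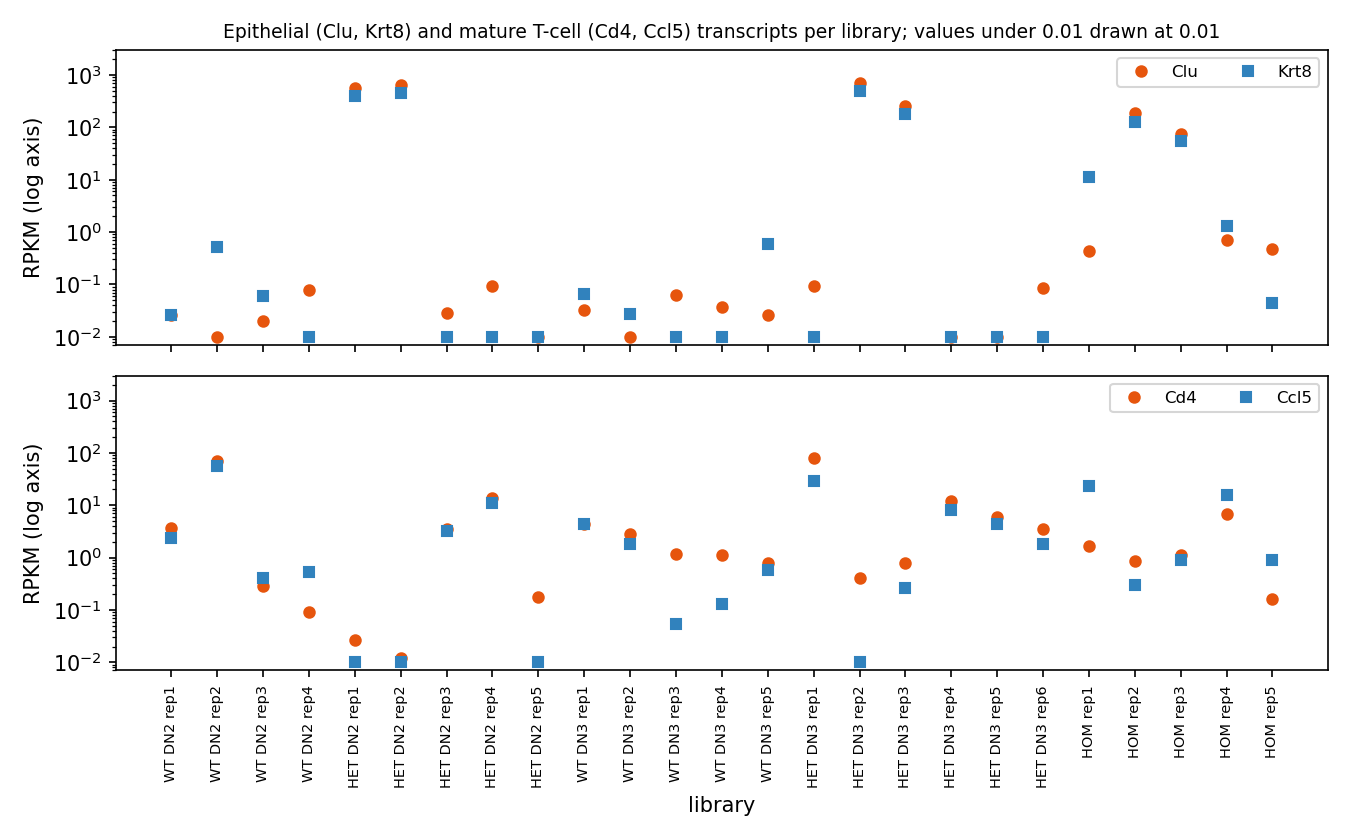
RPKM (log axes) of the epithelial genes Clu and Krt8 and of the mature T-cell genes Cd4 and Ccl5 in each of the 25 Lck libraries, 1 point per library, with values under 0.01 drawn at 0.01. Clu separates 6 libraries, and Cd4 is highest in WT DN2 replicate 2 and HET DN3 replicate 1, at 69.4 and 80.3 RPKM.

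The first comparison, Lck HOM against WT DN3, sets cells with both alleles floxed, whose label names no stage, beside WT DN3 cells. Kit and Cpa3, which are lower in DN3 than in DN2 cells, stood at 49.7 and 61.3 RPKM in HOM, against 9.43 and 5.97 in WT DN3 and 23.5 and 58.0 in WT DN2, so the comparison does not part genotype from stage. Bcl11b (chromosome 12, 109148613 to 109241624, build mm9) fell from 106.3 ± 13.5 RPKM in WT DN3 (SD, n = 5) to 49.6 ± 10.3 in HOM (n = 5), a log2 change of -1.13 (SE 0.12, adjusted p = 2.33e-07) or 2.19-fold. Both genes in the study's title rose. Id2 (chromosome 12, 25778664 to 25780957), an inhibitor of E-protein transcription factors, went from 3.90 ± 0.513 to 54.1 ± 6.39 RPKM (log2 change 3.77, SE 0.68, adjusted p = 1.38e-04), and Zbtb16 (chromosome 9, 48462402 to 48644050), which encodes the innate-lymphocyte factor PLZF, went from 0.0338 ± 0.0402 to 17.7 ± 2.99 RPKM (log2 change 8.77, SE 0.55, adjusted p = 6.98e-11). Exact 2-sided permutation tests of these 3 genes gave p = 0.00794 each, the smallest that 5 against 5 libraries allow (adjusted p = 0.0217 over the 30 tests).

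In all, 4820 of 12218 genes tested were called in HOM against WT DN3, 2418 higher and 2402 lower, and 1439 changed at least 2-fold (876 higher, 563 lower). Without the 6 libraries 4899 genes were called, of which 4215 were among the 4820, and without the 8 libraries 5466, of which 4435 were. The higher genes that the naming rule took had almost no RNA in WT DN3. Dapl1 rose at least 1480-fold, from no counts to 53.7 ± 29.9 RPKM. Trpm1, a cation channel gene, rose by 9.17 (SE 1.32, adjusted p = 9.49e-06), and Cxcr5, a chemokine receptor gene of follicular lymphocytes, by 7.91 (SE 1.67, adjusted p = 7.20e-04). Npffr1, Zfp105 and Krt7, with 1 to 3 counts in WT DN3, stood at 16, 6.76 and 9.55 RPKM in HOM. Clu and Krt7 belong to the epithelial transcripts of HOM replicates 2 and 3: Clu changed by 10.42 with all libraries and by 3.87 without the 6, and Krt7 was no longer called (adjusted p = 0.187). At the other end, Scn4b, a sodium channel subunit gene, fell from 29.0 ± 11.2 to 0.444 ± 0.573 RPKM (log2 change -6.03, SE 0.68, adjusted p = 4.28e-07). Fam163b fell from 49.6 to 1.16 RPKM and the thymus-homing receptor gene Ccr9 from 13.8 ± 4.78 to 0.489 ± 0.259. Dgkeos, Myl10, Gtf2ird1 and Camkv fell by 3.68, 3.67, 3.57 and 3.52 on the log2 scale.

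T-lineage genes fell more often than they rose. Of 27 measured members of the T-lineage identity list, 13 fell, 2 rose and 12 did not pass (14 and 2 adjusted over the list alone). Camera placed the list below the other genes at a preset correlation (adjusted p = 0.0251), but gave adjusted p = 0.998 with an estimated correlation. Cd3d, a subunit of the T-cell receptor complex, fell from 221 ± 34 to 75.4 ± 19.6 RPKM (log2 change -1.58, SE 0.18, adjusted p = 6.16e-07), Cd3e from 379 to 204 RPKM, and Dntt, which adds nucleotides at antigen receptor joins, from 681 ± 62.6 to 359 ± 47.5. Themis, a T-cell signalling gene, rose from 34.1 ± 1.70 to 61.2 ± 4.82 RPKM. Of 11 double-positive thymocyte genes 5 fell and none rose (5 adjusted over the list alone), among them Ccr9 and Arpp21 (log2 change -0.73); camera gave adjusted p = 0.108 and fry, which asks whether the genes of a list move one way, 1.82e-04. The gamma-delta T list moved both ways, with 2 of 9 higher and 3 lower (2 and 4 adjusted over the list alone): Sox13 fell from 26.9 to 6.69 RPKM, and Cd163l1 rose from 18 to 427 ± 78.8 RPKM and the protease gene Cpa3 by 3.27 (6.07 without WT DN3 replicate 5, which had 26.2 RPKM where the other 4 had 0.804 to 1.02).

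Natural killer (NK) and group 1 innate lymphoid (ILC1) genes went the other way. Of 14 measured, 10 rose, 1 fell and 3 did not pass, with the same counts adjusted over the list alone and a median log2 change of 3.79. Camera gave adjusted p = 8.53e-06 at the preset correlation and adjusted p = 0.203 with an estimated correlation. Cd160, a receptor of NK and intraepithelial cells, rose from 1.26 ± 0.322 to 21.8 ± 4.30 RPKM (log2 change 4.07, SE 0.23, adjusted p = 1.69e-11), the signalling adaptor gene Fcer1g from 0.616 to 62.8 ± 13.1, and Nfil3, an early regulator of innate lymphoid cells, from 0.817 to 14.0. The NK receptor gene Cd244 rose by 4.46. Of 15 PLZF and innate-like T genes 5 rose and 1 fell (5 and 2 adjusted over the list alone), with the gut-homing integrin gene Itgb7 up by 3.54, the receptor gene Il12rb1 up by 1.16 and the inhibitory receptor gene Pdcd1 down (log2 change -1.89). Of 7 ILC2 and ILC3 genes 2 rose and 2 fell (3 and 2 adjusted over the list alone): Il9r, a cytokine receptor gene of ILC2, went from 3.38 ± 0.418 to 35.0 ± 7.23 RPKM, Il17rb rose by 0.34 and Ahr changed by -0.80.

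Cytokine receptor and homing genes rose in 9 of 20 cases and fell in 1, which was Ccr9 (9 and 2 adjusted over the list alone). Camera gave adjusted p = 0.019 at the preset correlation and adjusted p = 0.998 with an estimated correlation. Il7r, the receptor gene for the main survival cytokine of early thymocytes, rose from 32.5 ± 2.99 to 91.2 ± 9.28 RPKM (log2 change 1.46, SE 0.12, adjusted p = 6.22e-09), and the integrin gene Itga4 from 46.1 to 134. In the stem and progenitor list 4 of 17 rose and 7 fell (4 and 8 adjusted over the list alone). Kit, the stem cell factor receptor gene, rose from 9.43 ± 3.46 to 49.7 ± 9.81 RPKM and Flt3 by 6.23 to 1.27 RPKM, whereas Gfi1b and Bcl11a changed by -3.64 and -1.66. The Notch list had 4 of 14 higher and 3 lower (4 and 4 adjusted over the list alone). The Notch target genes Heyl and Nrarp rose by 4.39 and 2.22 and Trib2 by 1.65, and the receptor gene Notch3 fell from 111 ± 18.5 to 29.6 ± 10.3 RPKM. Of 6 E-protein and Id genes 4 were higher and 2 lower, the same adjusted over the list alone; Tcf4 and Tcf12 rose by 0.53 and 0.46, and Tcf3, the gene of E2A, changed by -0.57.

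Camera called none of the other lists. Of 23 Bcl11b cofactor genes, 1 rose and 8 fell (the same adjusted over the list alone): Runx3, a transcription factor gene of cytotoxic and innate lineages, rose from 16.5 to 41.7 RPKM, and Mbd3, Mta1 and Cbx2 changed by -0.58, -0.40 and -0.52. Of 19 cell-cycle genes 3 fell (Ccnd2, Ccnd3, Mcm2), of 14 p53 and apoptosis genes 3 fell and 1 rose (Cdkn1a -1.86, Bcl2 -0.77, Bcl2l11 -0.57, Trp53inp1 0.56), both with the same counts adjusted over the list alone. Of 15 immediate-early and heat-shock genes Nr4a1 fell (-2.28) and Atf3 was called higher, at least 21.3-fold; adjusted over the list alone, 1 fell. Of 5 B-cell genes the coactivator gene Pou2af1 rose from 2.30 to 37.0 RPKM and Cd79b changed by -1.11 (1 and 2 adjusted over the list alone), and of 13 myeloid and dendritic genes Cebpb rose by 0.77 while Irf8 and Lyz2 changed by -0.89 and -2.25, the same adjusted over the list alone. In the thymic stroma list of 4, Epcam fell from 22.4 to 6.37 RPKM, Pecam1 rose by 0.68, and Krt8 was called at 7.75 (39.5 ± 54.7 RPKM in HOM), moving with the epithelial transcripts of HOM replicates 2 and 3; without the 6 libraries its change was 4.76 (the same counts adjusted over the list alone). None of 5 erythroid and none of 5 sex-linked genes passed edgeR's test over all genes or over the list alone; Hba-a1 had adjusted p = 0.104 and Xist 0.161. The median and the direction of camera had opposite signs for the Notch, ILC2 and ILC3, myeloid, immediate-early and p53 lists, none of which camera called.

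**Figure D2:**
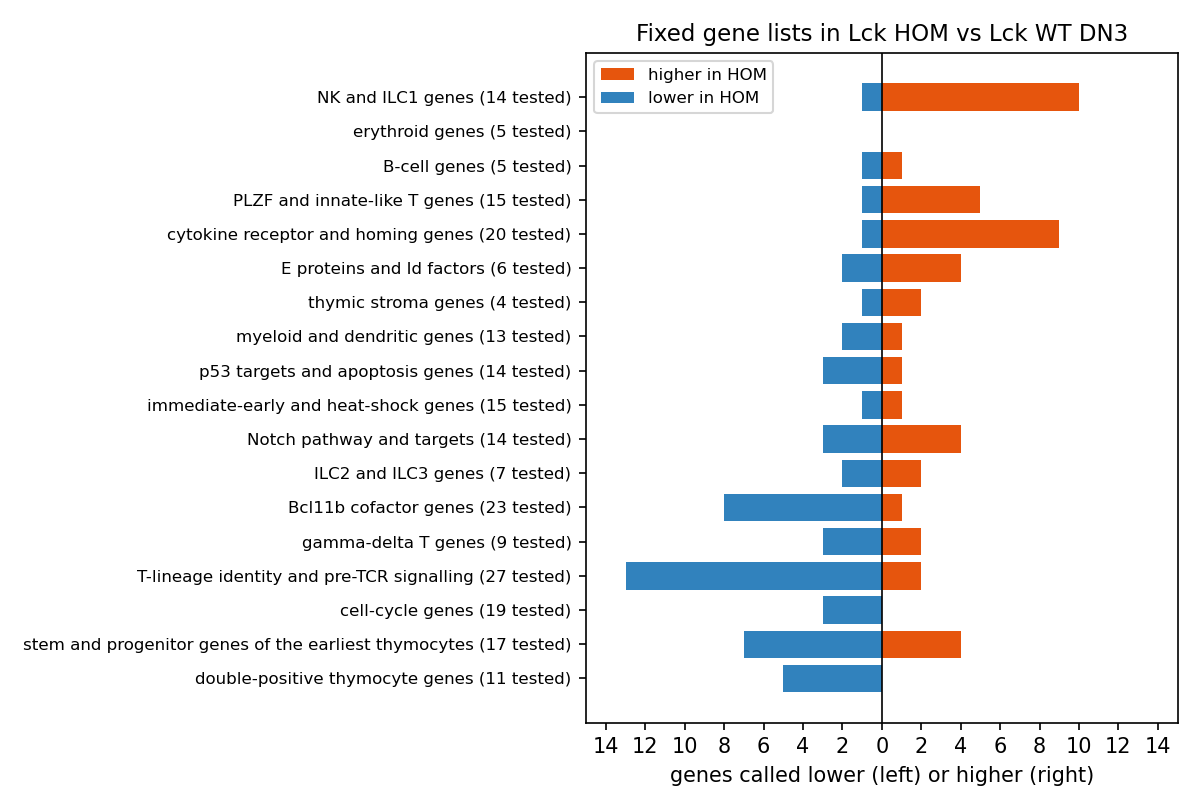
Number of genes called higher and lower in Lck HOM than in Lck WT DN3 (x axis, genes) for 18 of the fixed lists (y axis). NK and ILC1 genes have 10 members called higher and T-lineage genes 13 called lower.

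Lck HOM against HET DN3 sets cells with 2 floxed alleles beside cells with 1, from the same sort. Kit and Cpa3 stood at 49.7 and 61.3 RPKM in HOM, 10.2 and 4.21 in HET DN3, and 25.2 and 56.5 in HET DN2. This comparison therefore does not part the second allele from stage either. Bcl11b was 104 ± 11.8 RPKM in HET DN3 (n = 6) and lower in HOM (log2 change -1.06, SE 0.12, adjusted p = 5.67e-07; exact 2-sided permutation p = 0.00216, adjusted p = 0.0217). Zbtb16 was 153-fold higher in HOM than the 0.116 ± 0.0551 RPKM of HET DN3 (log2 change 7.25, SE 0.46, adjusted p = 2.81e-10). Id2 stood at 19.1 ± 15.9 RPKM in HET DN3 and did not pass edgeR's test (log2 change 1.5, SE 0.58, adjusted p = 0.0623). Without the 6 libraries it was called (2.36, adjusted p = 0.00753), and the exact 2-sided permutation test with all 11 libraries gave p = 0.00649 (adjusted p = 0.0217).

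Calls numbered 3034 in this comparison (1443 higher, 1591 lower; 887 at least 2-fold), 2759 without the 6 libraries and 3366 without the 8. Dapl1 rose from 0.110 to 53.7 RPKM, Npffr1 from 0.0740 to 16, the signalling ligand genes Wnt6 and Fgf3 from 0.0524 and 0.128 to 10.2 and 12.9, and Trpm1 and Fcer1g by 6.89 and 5.66. Scn4b fell from 10.9 to 0.444 RPKM (log2 change -4.58, SE 0.64, adjusted p = 1.05e-05), Ccr9 by 4.30 on the log2 scale, and Matk, a kinase gene, from 12.9 to 1.35 RPKM (SE of the log2 change 0.29, adjusted p = 2.87e-08). Fam163b, Vwce, Dgkeos, Camkv and Gtf2ird1 changed by -3.66, -3.31, -3.30, -3.22 and -3.11. Of the T-lineage genes 11 fell and 2 rose (13 and 2 adjusted over the list alone; camera adjusted p = 0.0308, and adjusted p = 0.794 with an estimated correlation), with Cd6 going from 22.9 to 3.38 RPKM and Cd3d changing by -1.35. Of the NK and ILC1 genes 7 rose (8 adjusted over the list alone; camera adjusted p = 4.39e-05, and adjusted p = 0.292 with an estimated correlation), with Cd160 up by 2.20 and the adaptor gene Tyrobp by 3.55. Double-positive genes fell in 6 of 11 cases (6 adjusted over the list alone; camera adjusted p = 0.0147, and adjusted p = 0.292 with an estimated correlation).

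Immediate-early and heat-shock genes fell in 3 of 15 cases (5 adjusted over the list alone): Nr4a1 by 2.25, Jun by 1.64 and the phosphatase gene Dusp1 by 1.23 on the log2 scale. Camera gave adjusted p = 0.0147 for them, and adjusted p = 0.794 with an estimated correlation. Gamma-delta T genes fell in 5 cases and rose in 2 (the same adjusted over the list alone), with Sox13 at -1.72, Id3 at -1.09 and Cd163l1 at 3.70. In the stem list 3 rose and 5 fell (the same adjusted over the list alone; Kit 2.29), in the Notch list 3 and 3 (4 and 3 adjusted over the list alone; Heyl 2.72, Notch3 -1.52, Notch1 -0.78), and in the cytokine receptor and homing list 5 and 3 (the same adjusted over the list alone; Il7r 0.86, Itga4 0.98). PLZF-type genes rose in 3 cases and fell in 4 (5 and 6 adjusted over the list alone), among them Pdcd1 at -2.32 and Itgae at -2.27; the median of the list was -0.77, while camera placed it higher, without a call (adjusted p = 0.814). HET DN3 replicate 1, with transcripts of mature T cells, belongs to the group with the higher values of these genes. Runx3 alone of the cofactor list passed (1.38).

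The third comparison, HET DN3 against WT DN3, asks whether 1 floxed allele changes expression. Bcl11b did not differ beyond the spread between libraries (log2 change -0.07, SE 0.12, adjusted p = 0.718; exact 2-sided permutation p = 0.777). The cytokine receptor genes Il7r and Il9r were higher in HET DN3: Il7r went from 32.5 ± 2.99 RPKM (n = 5) to 50.4 ± 5.0 (n = 6; log2 change 0.60, SE 0.12, adjusted p = 0.0148), and Il9r from 3.38 ± 0.418 to 12.4 ± 4.19 (1.83, SE 0.43, adjusted p = 0.025). The Notch target gene Heyl went from 1.13 ± 0.0472 to 3.72 ± 1.56 RPKM (1.67, SE 0.39, adjusted p = 0.0247) and Cd160 from 1.26 ± 0.322 to 4.76 ± 1.22 (1.87, SE 0.21, adjusted p = 5.96e-05). These 4 were also called without the 6 libraries (adjusted p = 0.0137, 1.45e-06, 0.00965 and 4.23e-04). Cd160 was called whichever single library was left out. Il7r was not called without WT DN3 replicate 3 (adjusted p = 0.0661), Heyl not without WT DN3 replicates 3, 4 or 5 or HET DN3 replicate 3 (adjusted p from 0.051 to 0.103), and Il9r not without these or HET DN3 replicate 1 (adjusted p from 0.0515 to 0.105).

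**Figure D3:**
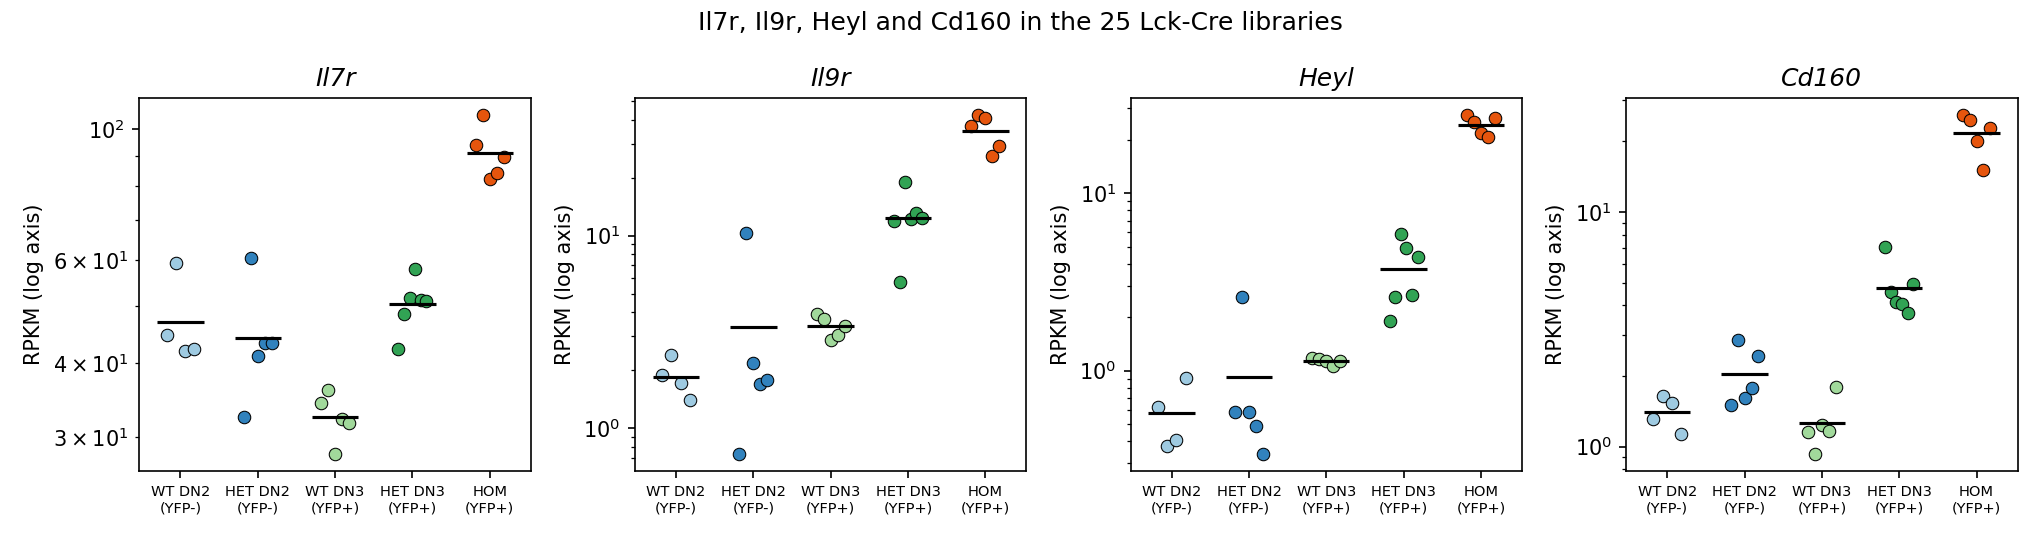
RPKM (log axis) of Il7r, Il9r, Heyl and Cd160 in each of the 25 Lck libraries, by group, with bars at the group mean. Il7r averages 32.5 RPKM in WT DN3, 50.4 in HET DN3 and 91.2 in HOM.

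Id2 was called higher in HET DN3 (log2 change 2.27, SE 0.63, adjusted p = 0.0385). The exact 2-sided permutation test gave p = 0.00649 (adjusted p = 0.0217). The highest Id2 values, 49.1 and 23.5 RPKM, are those of replicates 2 and 3, which carried epithelial transcripts. Every HET DN3 library lay above every WT DN3 library (lowest 6.44, highest 4.70 RPKM). Without the 6 libraries the Id2 change was 1.40 and not called (adjusted p = 0.131). Without the 8 it was 1.13 and called (SE 0.21, adjusted p = 0.0217). The call was lost without any 1 of the WT DN3 libraries or HET DN3 replicate 1, 2 or 3 (adjusted p from 0.061 to 0.119). Zbtb16 did not pass (1.52, adjusted p = 0.0631; exact permutation p = 0.0195, adjusted p = 0.0390). The total of 900 called genes (526 higher, 374 lower; 188 at least 2-fold, 180 of them higher) depended on the libraries used: 212 were called without the 6 (155 higher, 57 lower; 175 of them among the 900) and 75 without the 8 (70 higher, 5 lower; 63 among the 900). Leaving out single libraries gave between 10 (without WT DN3 replicate 3) and 1662 (without HET DN3 replicate 5), and 506 and 98 without HET DN3 replicates 2 and 3, which carried epithelial transcripts. S100a6 changed by 8.43 (155 ± 260 RPKM in HET DN3) and by 4.49 without the 6, and Rhoc by 5.66 and then 1.54, no longer called (adjusted p = 0.108). Ahnak (4.13, then 3.91) and Dusp6 (2.07, then 1.55) were not called either (adjusted p = 0.076 and 0.119). Tigit, an inhibitory receptor gene of T cells, stood at 47.5 RPKM in HET DN3 replicate 1; its change was 5.57, 6.02 without the 6 (adjusted p = 0.0613), 3.33 without that library (adjusted p = 0.124) and 2.37 without the 8 (adjusted p = 0.29). Fbp1, a gluconeogenic enzyme gene, rose from 2.52 to 12.2 ± 8.27 RPKM and was also called without the 6 (adjusted p = 0.0232), but not when any 1 of the WT DN3 libraries or HET DN3 replicate 1, 3 or 4 was left out (adjusted p from 0.0506 to 0.118). Lower genes named were Fam163b (-1.77), Crip1 (447 against 810 RPKM), Pcbp3 (-0.73), Cdc42ep4 (-0.70), Ccdc85c (-0.57), Def8 (-0.56), 4930427A07Rik (-0.56) and Chtf18 (-0.54); without the 6 libraries 2 of these 8 and 3 of the 8 higher genes were still called, and each of the 8 lower genes lost its call without at least 1 single library.

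No fixed list was called by camera with an estimated correlation in this comparison. NK and ILC1 genes had 2 of 14 higher (6 adjusted over the list alone), PLZF-type genes 1 of 15 (4) and cytokine receptor and homing genes 3 of 20 (6), with adjusted p = 0.00399, 0.00399 and 0.00315 at the preset correlation and adjusted p = 0.647 for each with an estimated correlation. Icos, a costimulatory receptor gene of activated T cells, was the PLZF-type member called (3.88), and Cxcr5 (7.26) and Itga4 (0.53) were called beside Il7r. Immediate-early and p53 genes had no member called over all genes and 5 and 6 adjusted over the list alone (adjusted p = 0.00399 each, and adjusted p = 0.647 with an estimated correlation). Myeloid and dendritic genes likewise had none of 13 called and 6 higher adjusted over the list alone (adjusted p = 0.314, and adjusted p = 0.704 with an estimated correlation), and S100a8, a gene of myeloid cells without counts in WT DN3, had a mean of 3.39 RPKM in HET DN3 (adjusted p = 0.0631). Cell-cycle genes had 2 of 19 lower, Mcm2 (-0.41) and Ccnd3 (-0.47), 2 adjusted over the list alone (adjusted p = 0.00315, and adjusted p = 0.654 with an estimated correlation). The globin gene Hba-a1 (9.0) was 1 of 2 erythroid calls (5 adjusted over the list alone), and Cd22 (6.69), Maf (2.74), Cd44 (3.56) and Id1 (3.49) were called in the B-cell, gamma-delta, stem and E-protein lists (3, 1, 1 and 3 higher adjusted over the list alone). T-lineage, cofactor and Notch lists each had 1 member lower (Skap1 -0.41, Mbd3 -0.44, Myc -0.34), as had the E-protein list (Tcf3 -0.42). These 4 calls and those of Icos and Id1 were lost without the 6 libraries, and 2 cytokine receptor and homing genes and 1 cell-cycle gene were left. Without HET DN3 replicate 1, the log2 changes of Hba-a1, Cd22, Maf, Icos, Cxcr5 and Cd44 were 1.53, 4.04, 0.897, 1.26, 1.89 and 3.165, none of them called (adjusted p = 0.671, 0.142, 0.157, 0.351, 0.0793 and 0.0528), and without the 8 libraries Cxcr5 alone of these 6 was called (2.25). Among uncalled genes, Krt8 had 9.27 (adjusted p = 0.0529).

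HET DN2 against WT DN2 asks the same before the reporter marks Cre activity. No gene passed edgeR's test, 912 had an unadjusted p under 0.05, and DESeq2 called 182 (181 higher, 1 lower). Without the 6 libraries 1 gene was called, Cp (ceruloplasmin, a copper-carrying oxidase), chosen after its value was seen (log2 change -5.0, adjusted p = 0.00887). Bcl11b stood at 145 ± 15.1 RPKM in HET DN2 (n = 5) and 148 ± 12.4 in WT DN2 (n = 4; log2 change -0.01, adjusted p = 0.994; exact 2-sided permutation p = 0.754). Id2 (0.68, adjusted p = 0.907) and Zbtb16 (0.09, adjusted p = 0.992) did not pass, and Id2 was 41.2 RPKM in WT DN2 replicate 2, which carried mature T-cell transcripts, and 49.5 RPKM in HET DN2 replicate 2, which carried epithelial ones. Over the lists alone 1 E-protein or Id gene was higher and 1 lower, and 1 stroma gene was higher. Camera placed T-lineage genes lower (adjusted p = 1.13e-08, and adjusted p = 0.17 with an estimated correlation) and immediate-early and heat-shock genes higher (2.59e-08, and adjusted p = 0.17 with an estimated correlation), with cell-cycle genes (0.0281) and cytokine receptor genes (0.043) lower at the preset correlation alone (adjusted p = 0.969 and 0.927 with an estimated correlation). Camera placed cell-cycle genes higher instead without the 6 libraries (adjusted p = 2.10e-05, and adjusted p = 0.639 with an estimated correlation) and no longer called cytokine receptor genes (adjusted p = 0.229). The heat-shock gene Hspa1a had 82.3 ± 45.9 against 15.1 ± 9.30 RPKM, the kinase gene Zap70 a change of -0.57 and Tcf7 one of -0.28.

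Whether the difference between HET and WT changes from DN2 to DN3 libraries was tested as an interaction. The DN2 libraries are YFP-negative and the DN3 libraries YFP-positive, so this test does not part stage from Cre activity. No gene passed edgeR's test, 1112 had an unadjusted p under 0.05, and array weights gave 170 calls (107 higher, 63 lower) and DESeq2 20 (13 higher, 7 lower). Without the 6 libraries Cp (5.49) and Il9r (1.77) were called, and without the 8 Cp (5.10), Heyl (2.21), Il7r (0.67), Il9r (1.65) and Kifc3 (1.15), a kinesin gene; Cp, Kifc3 and the sets themselves were chosen after their values were seen. Over the lists alone 7 cytokine receptor, 5 PLZF-type, 2 NK and ILC1, 2 p53 and 2 erythroid genes were more raised in DN3, and none of them over all genes. WT DN2 replicate 2 and HET DN3 replicate 1, with transcripts of mature T cells, both raise this difference for genes that are high in them. Camera gave adjusted p = 1.15e-06, 2.46e-05 and 0.00137 for the first 3 of these lists and 0.0306 for T-lineage genes, and adjusted p = 0.331, 0.331, 0.331 and 0.704 with an estimated correlation.

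WT DN3 against WT DN2 follows the stages and the reporter in cells with unaltered Bcl11b. Bcl11b was lower in DN3 (log2 change -0.40, SE 0.13, adjusted p = 0.0287; exact 2-sided permutation p = 0.0159), as was Zbtb16 (-2.52, adjusted p = 0.00159), at 0.0338 against 0.235 RPKM. Id2 did not pass (-1.76, adjusted p = 0.0617). Progenitor genes fell: of 17 stem and progenitor genes 8 were lower and 1 higher (10 and 1 adjusted over the list alone; camera adjusted p = 1.02e-04, and adjusted p = 0.618 with an estimated correlation), among them Kit (-1.24), Runx2 (-1.28) and Etv6 (-0.66), with Zfpm1 higher (0.64). Cpa3 went from 58.0 ± 6.49 to 5.97 ± 11.3 RPKM (n = 4 and 5; log2 change -3.14, adjusted p = 0.006); 26.2 RPKM of it was in WT DN3 replicate 5. Lef1, a T-cell transcription factor gene, rose from 38.2 ± 28.6 to 117 ± 29.9 RPKM and Rag1, a recombinase gene, from 99.2 to 154.

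Cytokine receptor and homing genes fell in 8 of 20 cases (8 adjusted over the list alone; camera adjusted p = 0.00187, and adjusted p = 0.864 with an estimated correlation), with Il4ra changing by -2.31. Cell-cycle genes rose in 4 of 19 (5 adjusted over the list alone; adjusted p = 0.00187, and adjusted p = 0.864 with an estimated correlation), such as Ccne1 (0.78) and Mcm2 (0.51); without the 6 libraries, none of them WT, 14 were called higher and 1 lower. NK and ILC1 genes had 1 higher and 4 lower (1 and 5 adjusted over the list alone), PLZF-type genes 1 and 5 (1 and 8) and T-lineage genes 5 and 2 (5 and 2); WT DN2 replicate 2, with transcripts of mature T cells, lies on the side where NK-type and homing genes were higher. Etv5, Tnfrsf8, Syt13, Arsi and Bcat1 rose by 1.96, 2.39, 3.36, 2.28 and 2.18, and Samhd1, Fndc1, Klf2 and Bpifc changed by -3.69, -3.11, -2.73 and -2.72. The survival gene Bcl2 went from 31.6 to 12.8 RPKM. The test called 2622 genes, 1486 higher and 1136 lower, with 300 at least 2-fold (59 higher, 241 lower), and 3137 without the 8 libraries, 4497 with only the groups compared and 6171 with array weights. Higher genes made up 56.7% of calls, but 38.7% with limma on log2(RPKM + 1).

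The same step in HET cells, HET DN3 against HET DN2, gave 1329 calls, 777 higher and 552 lower (201 at least 2-fold: 65 higher, 136 lower), 1011 without the 8 libraries, 838 without HET DN3 replicate 5, 461 with only the groups compared and 2178 with array weights. Bcl11b was again lower in DN3 (-0.46, SE 0.12, adjusted p = 0.0134; exact 2-sided permutation p = 0.00433, adjusted p = 0.0217), and Id2 (-0.17, adjusted p = 0.887) and Zbtb16 (-1.09, adjusted p = 0.107) did not pass. Stem and progenitor genes fell in 10 of 17 cases and rose in 1 (12 and 1 adjusted over the list alone; camera adjusted p = 2.58e-07, and adjusted p = 0.18 with an estimated correlation): Lyl1 went from 14.8 to 0.884 RPKM, Spi1, the gene of the myeloid factor PU.1, from 6.01 to 0.620, and Cd34 changed by -6.65. T-lineage genes rose in 6 cases and fell in 2 (7 and 3 adjusted over the list alone; adjusted p = 0.0193, and adjusted p = 0.979 with an estimated correlation), with Zap70 up from 19.4 to 48.4 RPKM, Lef1 from 26.4 to 110 and Rag1 by 0.84. Cell-cycle genes had 1 member higher (adjusted p = 0.0193, and adjusted p = 0.979 with an estimated correlation). Camera called neither list without the 6 libraries (adjusted p = 0.139 and 0.336). Cpa3 went from 56.5 to 4.21 RPKM, Fgf3 from 7.01 to 0.128, and Arsi from 2.22 to 17.2. Il9r and Heyl rose by 1.91 and 2.03, Cd160 by 1.25 and Id3 by 1.40. Both stages include 2 libraries with epithelial transcripts. Fold changes of the WT and HET steps correlated across the 12218 genes (r = 0.237, rho = 0.548, 72.2% with the same sign), and genes are not independent replicates.

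Lck HOM against WT DN2 sets the mutant cells beside the earlier stage. Bcl11b was 2.88-fold lower (log2 change -1.53, SE 0.13, adjusted p = 8.69e-09), Id2 rose by 2.01 (SE 0.68, adjusted p = 0.0216) and Zbtb16 by 6.25 (SE 0.52, adjusted p = 7.71e-09), each with exact 2-sided permutation p = 0.00794 (adjusted p = 0.0217). The progenitor gene Erg went from 23.1 to 3.59 RPKM, Bcl11a and Runx2 changed by -2.78 and -2.31, and 10 of 17 stem and progenitor genes fell while 3 rose (the same adjusted over the list alone; camera adjusted p = 0.00738, and adjusted p = 0.924 with an estimated correlation). NK and ILC1 genes rose in 7 of 14 cases and fell in 1 (the same adjusted over the list alone; 0.00738, and adjusted p = 0.924 with an estimated correlation). Ccr9 went from 24.8 to 0.489 RPKM, Cd3g from 1227 to 357 and Bcl2 from 31.6 to 7.63, and T-lineage genes fell in 12 cases and rose in 5 (the same adjusted over the list alone). Necab1, a calcium-binding protein gene, rose from 0.0842 to 26.1 ± 6.50 RPKM and Npffr1 at least 647-fold. In total 5034 genes were called, 2599 higher and 2435 lower, 1483 of them at least 2-fold, and 5864 without the 8 libraries.

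The Vav series asks whether deletion before thymus entry changes the same genes. Bcl11b went from 14790 ± 5497 scaled counts in WT (n = 2) to 12690 ± 1378 in HET (n = 4) and 5109 ± 238 in HOM (n = 3), with log2 changes of -1.53 (SE 0.22, adjusted p = 7.86e-05) in HOM against WT and -0.22 (adjusted p = 0.749) in HET against WT. Id2 rose from 103.5 ± 14.1 to 1402 ± 175 in HOM (log2 change 3.76, SE 0.23, adjusted p = 5.80e-07) and Zbtb16 from 23.4 ± 7.69 to 2333 ± 429 (6.66, SE 0.64, adjusted p = 6.99e-06). With 3 against 2 libraries the exact 2-sided permutation test cannot go below p = 0.10, its value for each of the 3 genes. Of the 2076 listed genes 2063 were called in HOM against WT (965 higher, 1098 lower) and 2076 in HOM against HET (972 higher, 1104 lower). The list was chosen on these libraries, so neither these counts nor those adjusted over a list alone are independent evidence.

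Among the listed genes, NK and ILC1 genes were higher in Vav HOM than WT in 19 of 20 cases and lower in 1, and cytokine receptor and homing genes in 8 and 2 of 10; counts adjusted over the list alone were the same. Cd160 rose by 4.70, Nfil3 by 4.50, Fcer1g by 5.17 and Il2rb, an interleukin-15 receptor subunit gene, by 5.98. PLZF-type genes had 7 higher and 2 lower, and Notch genes 4 and 2 (Heyl 5.15, Nrarp 3.41, Notch3 -2.07). T-lineage genes had 7 of 8 lower (Cd3d from 5435 to 888 scaled counts, Dntt -2.26, Cd3g -2.48) and 1 higher, Cd2, from 35.1 to 1333. Stem genes had 3 higher and 6 lower, gamma-delta genes 1 and 4 (Sox13 -4.69, Cd163l1 4.48), myeloid genes 1 and 4 (Lyz2 -4.03), and immediate-early genes 5 lower (3 adjusted over the list alone). Fam163b went from 2091 to 7.27 scaled counts, Scn4b from 1484 to 6.04 and Ccr9 from 1350 to 15.2, and Dapl1 rose from 21.6 to 3594 ± 772 and Hecw2, a ubiquitin ligase gene, from 3.95 to 841. Against HET, Bcl11b changed by -1.31, Id2 by 3.02 and Zbtb16 by 5.71 in HOM (exact 2-sided permutation p = 0.0286 each, adjusted p = 0.0477), with Npffr1 at 432 against 0.356 scaled counts, Dapl1 at 9.06 and Dgkeos at -6.36.

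Vav HET against Vav WT asks again what 1 floxed allele changes, and 46 of the listed genes were called, 37 higher and 9 lower. Il9r rose from 162 ± 12.4 to 925 ± 109 scaled counts (log2 change 2.52, SE 0.20, adjusted p = 1.97e-04), Heyl from 75.9 to 302 (1.99, adjusted p = 0.00122), Fbp1 from 74.6 to 356 (2.26, adjusted p = 9.36e-04), and Necab1, Cd160 and the granzyme gene Gzma by 2.36, 1.63 and 1.30. Fam163b and Scn4b changed by -2.96 and -2.95, and the cell-cycle inhibitor gene Cdkn1a by -0.98. NK and ILC1 genes had 2 of 20 called (3 adjusted over the list alone) and Notch genes 1 of 6 (2 higher and 1 lower). Id2 (0.74, adjusted p = 0.083; exact permutation p = 0.0667, the smallest possible) and Zbtb16 (0.95, adjusted p = 0.497) did not pass. The count was 24 without WT replicate 1, 28 without WT replicate 2, 30 without HET replicate 2 and 63 without HET replicate 4, and DESeq2 called 140.

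Genes called in both HOM comparisons overlapped in the same direction. Of 658 genes called higher in Vav HOM and tested in the Lck table, 584 were also higher in Lck HOM, where independent lists would share 130.2. Of 923 called lower 672 were shared, against 181.5 (Fisher's exact test across genes, 1-sided for a larger overlap, p = 2.56e-297). Another 2 genes went opposite ways. Fold changes correlated at r = 0.911 (rho = 0.896) over 1587 genes, which are not independent replicates and were selected for changing in the Vav series, and 96.7% had the same sign. The difference between the Lck and Vav changes passed edgeR's test for 126 of 2066 genes, 118 of them with the higher value in Lck, for 223 without the 8 libraries, and for between 22 (without Vav HOM replicate 1) and 216 (without Lck HOM replicate 1) when single libraries were left out. The Vav scale rests on centring the gap, and an error in it would move all of these differences the same way. Of 8 T-lineage genes in this test 5 differed, the same adjusted over the list alone: Cd3d changed by -1.58 in Lck HOM and -2.61 in Vav HOM, Cd3e by -0.92 and -1.96, and Dntt by -0.95 and -2.26. Sox13 changed by -2.03 and -4.69, Epcam by -1.84 and -4.08.

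**Figure D4:**
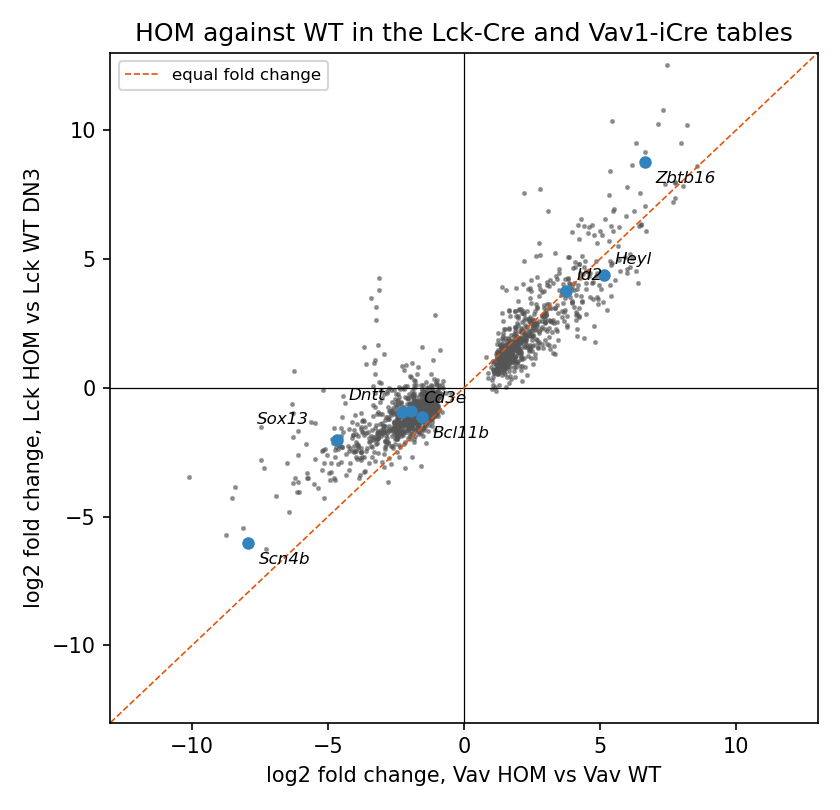
Log2 fold change of each gene in Vav HOM against Vav WT (x axis) and in Lck HOM against Lck WT DN3 (y axis), 1 point per gene tested in both tables, with a dashed line where both are equal. Across 1587 genes r is 0.911, and many of the genes that fell in Vav HOM lie above the line.

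A further question is whether HOM cells keep the expression program of the DN2 to DN3 step of HET cells. In that step YFP-negative cells are set beside YFP-positive ones, so stage and loss of 1 allele are not parted. Il9r rose from 3.34 to 12.4 RPKM in HET cells and from 1.85 to 3.38 in WT cells. Cd160 went from 2.03 to 4.76 RPKM in HET cells and from 1.41 to 1.26 in WT cells. In Lck HOM against WT DN3, the 65 genes that rose at least 2-fold from HET DN2 to HET DN3 had a median log2 change of 0.24, with 27 called higher and 13 lower (camera p = 0.0039, p = 0.20 with an estimated correlation). The median was 0.66 without the 6 libraries and -0.03 over the 777 genes of the list without the 2-fold limit. The 136 genes that fell had a median of -0.22, of which 36 were called higher and 39 lower, and camera gave p = 0.86, and p = 0.968 with an estimated correlation. Leaving out single libraries moved this median between -0.450 and 0.354. Genes called at least 2-fold in Vav HOM against WT served as a second pair of lists. In Lck HET DN3 against WT DN3, the 655 higher ones had a median of 0.66, with 123 called higher and 2 lower and 90.4% above 0 (camera p = 3.86e-20, p = 0.00185 with an estimated correlation), and the median was 0.41 without the 8 libraries, with 39 called higher. Leaving out WT DN3 replicates 1 to 5 gave 41, 51, 5, 29 and 54 called higher, and leaving out HET DN3 replicates 1 to 6 gave 25, 75, 30, 89, 197 and 173. Quantile normalization, run with limma on log2(RPKM + 1), gave 9 and a median of 0.184, and limma with a pseudocount of 0.1 gave 73 and 0.57. The 896 lower ones had a median of -0.10, with 2 called higher and 21 lower (camera p = 7.99e-04, p = 0.411 with an estimated correlation). In Lck HOM the medians were 1.94 and -1.09.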

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

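The counts without 8 libraries given here were chosen after the result was seen. Among 69 sets of 4 to 6 library values, 1 set per group and per gene or total count, 11 held a library far from the others by Dixon's test at the 95% level. Chance puts about 1 in 20 sets past that limit, but the sets share libraries and are not independent. In WT DN2 replicate 2, which carried mature T-cell transcripts, Id2 was 41.23 RPKM, against 3.73 to 6.07 in the other 3 libraries, Il7r 59.16 (42.0 to 44.8) and Ccr9 53.14 (12.7 to 19.2). In WT DN3 replicate 5 Zbtb16 was 0.1045 RPKM (0.0113 to 0.0286 in the other 4), Kit 15.58 (7.41 to 8.36) and Cpa3 26.24 (0.804 to 1.02), values nearer to those of DN2. In HET DN2 replicate 2, with epithelial transcripts, Il9r was 10.31 RPKM (0.738 to 2.19 in the others) and Heyl 2.601 (0.341 to 0.588). In HET DN2 replicate 1 Kit was 18.37 RPKM (25.6 to 28) and Notch3 136.4 (83.7 to 96.2). In HET DN3 replicate 1 Cd160 was 7.105 RPKM (3.72 to 4.95 in the other 5).

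The change in HOM differed between the Lck and Vav series, in a test of the difference itself, for 126 genes, 118 of them with the higher value in Lck. Of the genes named in either comparison, those that fell less in Lck HOM (log2 difference, Lck minus Vav) included Hsf2bp (5.75, SE 1.02, adjusted p = 8.59e-04), Ttll9 (4.73, SE 0.67, adjusted p = 7.69e-05), Vwce (4.25, SE 0.74, adjusted p = 7.32e-04), Pak6 (3.64, adjusted p = 0.0143), Gm5111 (3.63, adjusted p = 0.0265), Cd6 (2.77, adjusted p = 0.0266) and Cdkn1a (2.665, adjusted p = 0.0341). Sox13, a gamma-delta T-cell factor gene, had 2.655 (SE 0.36, adjusted p = 7.69e-05), Dgkeos 2.60 (adjusted p = 0.0143), Epcam 2.24 (adjusted p = 0.00476), Camkv 2.24 (adjusted p = 0.016) and Runx2 2.15 (adjusted p = 0.0217). Among T-cell receptor and recombination genes the differences were 1.31 for Dntt (SE 0.25, adjusted p = 0.00154), 1.28 for Cd3g (adjusted p = 0.0217), 1.04 for Cd3e (adjusted p = 0.016) and 1.04 for Cd3d (adjusted p = 0.036). Npffr1 rose in both, with 1 count in Lck WT DN3, so that the fitted difference of 3.28 (adjusted p = 0.0416) rests on a group almost without counts and its size is not measured. All of these are edgeR quasi-likelihood tests. The count was 22 without Vav HOM replicate 1, 57 and 69 without Vav WT replicates 2 and 1, 67 without Vav HOM replicate 2, 208 and 216 without Lck HOM replicates 4 and 1, and 223 (191 higher in Lck, 32 lower) without the 8 libraries. The median difference over the 2066 genes was 0.43. An error in the scale of the Vav table would move all differences the same way, and the test was not rerun with other scales.

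Smaller falls in Lck HOM might come from cells that kept Bcl11b. Such cells would leave every strongly falling gene at the share of WT RNA they bring, but of 42 genes lower by at least 16-fold in Vav HOM, 38.1% had less than 50% of the median excess (25.5%) left in Lck HOM, with Scn4b at 1.53%, Fam163b at 2.33% and Ccr9 at 3.51% of their WT level. The tables therefore argue against undeleted cells as the whole cause. Selection of the Vav list on its own libraries predicts too large folds in both directions alike; the Lck to Vav ratio of the median log2 change was 0.581 for 897 lower and 0.907 for 656 higher genes, a difference of 0.326, which ranged from 0.268 to 0.394 when single libraries were left out, so selection cannot be told apart from a difference between the series. An error in the scale of the Vav table would move the ratios of lower and higher genes in opposite directions, and was not tested as a cause. The later action of Lck-Cre stays open as a biological explanation and was not tested.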

How the results depend on the processing

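The tests with DESeq2 and limma, the names as deposited and the counts without 6 or 8 libraries were chosen after seeing the data. Where a count or value below moved, the cause was not tested unless stated. The pseudocount of 0.1, quantile normalization and array weights also replaced the edgeR test by limma, so their counts do not show the effect of the named setting alone. Asking for a change of at least 2-fold, which by construction calls fewer genes, left 1439 in HOM against WT DN3, 887 in HOM against HET DN3, 188 in HET DN3 against WT DN3, 300 in WT DN3 against WT DN2, 201 in HET DN3 against HET DN2 and 1483 in HOM against WT DN2. With names as deposited, the shifted columns set values of different genes side by side and the counts were 9820 in HOM against HET DN3, 9301 in HET against WT DN3, 8057 in HET against WT DN2, 9536 and 9106 in the stage comparisons of WT and HET, 10538 in HOM against WT DN2 and 8364 for the interaction. HET DN3 against WT DN3 (900) moved with many settings: 408 with no filter, 1573 with the replicate block, 65 with only the groups compared, 458 with limma, 537 with a pseudocount of 0.1, 68 with quantile normalization, 2218 with array weights, 1877 with DESeq2, 212 without the 6 libraries and 75 without the 8. For HET DN2 against WT DN2 (0) the 6 and the 8 left out gave 1 each and DESeq2 182. For the interaction (0) they gave 2 and 5, array weights 170 and DESeq2 20. WT DN3 against WT DN2 had 4497 with only the groups compared and 6171 with array weights, and HET DN3 against HET DN2 had 461 and 2178. Equal replicate numbers, checked by the correlation of residuals across genes, were over 0.1 in 4 of 5 cases in HOM against HET DN3 (-0.00668 to 0.748) and 3 of 5 in HET DN3 against HET DN2 (-0.716 to 0.742, none matching best by its own number), so no pairing by number was shown there. Xist was high in HET DN2 replicates 1 and 5 and in HET DN3 replicates 2 and 6, and epithelial transcripts lay in replicates 1 and 2 and in replicates 2 and 3, so these groups may share animals under numbers shifted by 1, which neither the fit nor the splits take up. Vav HET against WT had 140 with DESeq2 and the Lck to Vav difference 223 without the 8.

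Leaving out single libraries gave 3925 to 4818 calls in HOM against WT DN3, 2387 to 3308 in HOM against HET DN3, 10 to 1662 in HET DN3 against WT DN3, 0 in HET DN2 against WT DN2 (0 to 0), 1794 to 2342 in WT DN3 against WT DN2, 838 (without HET DN3 replicate 5) to 1632 in HET DN3 against HET DN2, 4215 to 5108 in HOM against WT DN2, 0 to 1 in the interaction (Appl2, 2.46, adjusted p = 0.0135 without WT DN3 replicate 5), 1886 to 2034 in Vav HOM against WT, 2058 to 2074 in Vav HOM against HET, 24 to 63 in Vav HET against WT and 22 to 216 in the Lck to Vav difference. In HET DN3 against WT DN3 the counts were 258, 448, 10, 184 and 157 without WT DN3 replicates 1 to 5 and 87, 506, 98, 490, 1662 and 1464 without HET DN3 replicates 1 to 6, so each library moved it. The median of the stage genes higher in DN3 (0.24) ranged from 0.226 to 0.725, with 0.416 without HET DN2 replicates 2 or 3, 0.725 and 0.709 without HET DN2 replicates 4 and 5, and 0.614, 0.555, 0.555, 0.394, 0.725 and 0.555 without HET DN3 replicates 1 to 6; it was 0.179 and not called with quantile normalization and -0.0252 with no 2-fold limit. The stage genes lower in DN3 (-0.22) ranged from -0.450 (without HET DN2 replicate 2) to 0.354 (without WT DN3 replicate 5), with -0.0831 without HET DN2 replicate 3, -0.0403, -0.00766 and -0.335 without HET DN3 replicates 1, 2 and 6, and -0.0553 and -0.419 without HOM replicates 4 and 5. With no 2-fold limit their median was -0.193 and called, a call judged by camera at the preset correlation only. The Vav-called genes ranged from 1.89 to 2.03 and from -1.20 to -1.004 in HOM, and from 0.574 to 0.716 and from -0.142 to -0.0458 (without HET DN3 replicate 1; -0.0643 without WT DN3 replicate 4) in HET DN3. With quantile normalization their medians were 1.11 and -0.908 in HOM and 0.184 and -0.217 in HET DN3. Camera called 29 list tests over the 8 Lck comparisons at the preset correlation and 29 without the 6 libraries, 24 of them the same, and 0 with an estimated correlation; cell-cycle genes in HET DN2 against WT DN2 turned from lower (adjusted p = 0.0281) to higher (adjusted p = 2.10e-05), 4 calls were lost (T-lineage and cell-cycle genes in HET DN3 against HET DN2, T-lineage genes in the interaction, cytokine receptor genes in HET DN2 against WT DN2) and 4 gained (erythroid genes in HET DN3 against WT DN3, and ILC2 and ILC3, cell-cycle and p53 genes in the interaction); fry called 21. Of the exact tests of Bcl11b, Id2 and Zbtb16, 16 of 30 had p under 0.05, and 13 with quantile normalization.

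Among single genes, signs turned only where no setting called the gene. Bcl11b in HET DN3 against WT DN3 was 0.0385 with quantile normalization, in the exact test as in the fit. Bcl11b in HET DN2 against WT DN2 was 0.0139 with the Xist covariate, 0.00896 with the block, 0.124 with array weights, 0.00814 without the 6, 0.0173 without the 8, and 0.0380, 0.00356 and 0.0376 without WT DN2 replicate 1 and HET DN2 replicates 1 and 5 (lowest -0.0626 without WT DN2 replicate 3). Id2 there was -0.55 without the 6. Zbtb16 there was -0.0904 with quantile normalization (the same in the exact test), -0.0987 without the 8, and -0.175, -0.0824, -0.0204 and -0.0573 without WT DN2 replicates 2 and 4 and HET DN2 replicates 2 and 3 (highest 0.406 without WT DN2 replicate 1). Id2 in HET DN3 against HET DN2 was 0.0138 with the block, 0.0392 with array weights, 0.198 without the 6 (0.133 in the exact test), and 0.0297, 0.340 and 0.00425 without HET DN2 replicates 1 and 2 and HET DN3 replicate 5 (lowest -0.7305 without HET DN3 replicate 2). Bcl11b in Vav HET against WT was 0.219 without WT replicate 1 and -0.56 without replicate 2. Among values of named genes, 9267 kept direction and call under an alternative, 827 lost the call, 22 gained it and 23 turned. Of the named genes called, 64 of 71 in HOM against WT DN3 were called whichever library was left out, but 1 of 35 in HET DN3 against WT DN3. Other scales moved the median of the listed genes by -0.124 (total) in Vav HOM against WT, and by 0.122 (TMM) and -0.132 (total) in Vav HOM against HET. For the Vav table the pseudocount, the filters, quantile normalization and the Xist covariate were not run, as they need full libraries. For the Lck to Vav difference the pseudocount, quantile normalization and the other Vav scales were not run. Depth limits the folds of genes with few counts in a group, and the Vav depth is unknown.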

Other observations

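Of the tests below, those of thymic epithelium, of induction by loss of Bcl11b and of RNA from other cells in HET DN3 were chosen after the result was seen. Set beside WT DN2, HOM cells moved members of a single list both ways (edgeR quasi-likelihood, n = 5 and 4). The Notch list had 5 of 14 higher and 5 lower, the same adjusted over the list alone, with Heyl at 5.42, the Notch-modifying glycosyltransferase gene Lfng at -1.48 and Myc at 0.57. PLZF-type genes had 3 of 15 higher and 5 lower (3 and 6 adjusted over the list alone): the signalling adaptor gene Sh2d1a rose by 1.57 and Il4ra changed by -2.59. WT DN2 replicate 2, with transcripts of mature T cells, belongs to the group with the higher values of the genes that fell. Cytokine receptor and homing genes had 4 higher and 4 lower (the same adjusted over the list alone), with Il7r up by 1.00. Of 13 myeloid genes 3 fell (3 adjusted over the list alone), among them the lysozyme gene Lyz2 (-3.27) and the myeloperoxidase gene Mpo (-4.86, adjusted p = 0.0245). The cytotoxic granule gene Gzma rose by 2.45 and Il9r by 4.30.

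Along the DN2 to DN3 step of HET cells, members of further lists were called. Double-positive genes had 2 of 11 higher and 1 lower and gamma-delta T genes 3 of 9 higher and 2 lower (4 and 2 adjusted over the list alone), and camera called neither list (adjusted p = 0.605 and 0.962; directional fry adjusted p = 0.41 and 0.499). The NK receptor gene Cd244 changed by -2.57 and the granule gene Nkg7 by -1.88, while Gzma rose by 1.79. Among genes of innate lineages and survival, Runx3 changed by -0.90 and Bcl2 by -1.22. Xist and the Y-linked gene Ddx3y divided the Lck libraries: 6 had over 100 CPM of Xist and under 5 of Ddx3y (WT DN2 and WT DN3 replicates 4, HET DN2 replicates 1 and 5, HET DN3 replicates 2 and 6), 15 had over 20 of Ddx3y and under 5 of Xist, and 4 of the libraries with epithelial transcripts (HET DN2 replicate 2, HET DN3 replicate 3, HOM replicates 2 and 3) had both. The sex of the animals is not in the labels.

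The transcripts of simple epithelium in 6 Lck libraries may come from cells or RNA that entered the samples. Genes particular to thymic epithelium (Foxn1, Psmb11, Krt5, Krt14, Ccl25, Prss16, Dll4) reached a median of 0.0157% of Krt8 across the 6 libraries, 2.79% at most, which argues against thymic epithelial cells, and the sort for CD25 should also remove them. Induction by loss of Bcl11b, in the 4 HET libraries, is argued against by their levels, above all 5 HOM libraries for 5 of 5 genes (Clu, Krt7, Krt8, Krt18, Krt19; lowest HET and highest HOM library 329 and 230 CPM for Krt8). The same test of induction by loss of Bcl11b, in the 2 HOM libraries, did not decide, as the 5 genes differ. The 3 other HOM libraries reached at most 0.977%, 1.02% and 1.7% of the lowest of the 6 for Clu, Krt7 and Krt18, but 41% for Krt19 and 20.6% for Krt8 (HOM replicate 1). They had 0.77 to 1.29 CPM of Clu, against at most 0.167 in the 16 others. In HOM replicates 2 and 3, however, Clu stood at 1.45 and 1.32 of Krt8, against 1.4 to 1.45 in the 4 HET libraries. A common source in differing amounts is consistent with the order of 39 genes picked in HET DN2 replicate 2, which held in the 5 others (lowest r = 0.962 across genes). In the 4 of these libraries with a male pattern, Xist stood at 0.0877 to 0.101 of Krt8, so a candidate source is 1 female tissue sample, and its tissue stays open. The shared ratios and gene order argue against induction as the source of most of these transcripts in HOM replicates 2 and 3. A smaller induction in HOM cells stays open.

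As a list, genes higher in Vav HOM lay above 0 in Lck HET DN3 against WT DN3, though 123 of 655 were called higher (39 without the 8 libraries, 9 with quantile normalization and limma, 5 without WT DN3 replicate 3), and a candidate explanation is a partial effect of 1 floxed allele. RNA of other cells in the 8 libraries is argued against as the whole cause: without them the list's median was 0.41 (camera p = 0.00212 with an estimated correlation), against 0.66 with all. Smaller amounts in the HET DN3 libraries that were kept are not excluded. In HET DN3 replicates 4, 5 and 6 Cd4 was 11.8, 5.94 and 3.56 RPKM and S100a6 2.74, 1.49 and 3.63, against at most 4.37 and 0.887 in WT DN3. Of 43 genes called in Vav HET against Vav WT and tested here, 42 lay on the same side in HET DN3 against WT DN3 without the 8 libraries (97.7%), where 79.5% was expected from the other genes called in Vav HOM in the same mix of directions, so this count does not settle it. Of the 43, 13 were called, among which were Il9r (1.86), Necab1 (2.51), Heyl (1.77), Cd160 (1.69) and Fbp1 (2.22). The level of Bcl11b RNA did not differ beyond its spread in either HET group, so a lower level was not detected at this precision. That level does not measure the dose of working Bcl11b: with both alleles floxed, 45.7% of the RNA was left in Lck HOM and 34.5% in Vav HOM. The HET DN2 libraries are also YFP-negative, before the reporter marks Cre activity. The pattern was found and tested on the same data and stays a hypothesis.

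Counts of called genes were compared with those of other splits of the same libraries into groups of the same sizes. Of 70 splits of the possible 126 or 462, the real one included, the real one alone called as many genes in HOM against WT DN3 (4820, highest other 789), HOM against HET DN3 (3034, 2018), HET DN3 against WT DN3 (900, 19), WT DN3 against WT DN2 (2622, 1254, also among the 16 splits that part all 4 pairs), HET DN3 against HET DN2 (1329, 884) and HOM against WT DN2 (5034, 4084). This argues against chance but does not exclude it: not all splits were run, other splits mix groups that differ, and animals that groups may share were not taken up. The count for HET DN3 against WT DN3 was 10 without WT DN3 replicate 3 and 75 without the 8 libraries. The splits decide nothing for HET DN2 against WT DN2 (0, highest other 54) and for the interaction (0, 1058, in 70 drawn from 58212), as 70 of 70 splits reach a real count of 0, or for Vav HOM against HET (2076, highest other of 35 splits 331), whose genes were selected on the same libraries. For HET DN2 against WT DN2 and for the interaction, 3 and 9 of the other splits called any gene, and what set those splits apart was not tested. For list medians in HOM against WT DN3, the real split alone was as far from 0 for the Vav-called genes (1.94, highest other 1.203, and -1.09, highest other -0.75). It was not for the stage genes (0.24 against 0.35, 6 of 70 splits as large, and -0.22 against 0.73, 44 of 70). In HET DN3 against WT DN3 the real split alone was as far from 0 for the Vav-called higher genes (0.66 against 0.57), but not for the lower (-0.10 against 0.21, 14 of 70).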
